A study of Homo sapiens with 10 samples.

How the data were processed

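RNA was sequenced from 10 libraries labelled as MOLM-14, a human acute myeloid leukaemia cell line. The cells received DMSO or TFMB-2HG, a cell-permeable ester of the oncometabolite 2-hydroxyglutarate (2-HG), at 125, 250, 500 or 1000 µM. Each of the 5 groups had 2 libraries and treatment lasted 6 days. Per the labels' protocols, total RNA was extracted with Trizol and libraries followed standard Illumina protocols. The kit, its strand setting and the read length are not given in the sources used here. The sample labels give the lowest dose as 125 µM and the series' design text as 100 µM; the sample labels were followed.

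The values analysed were TPM, a measure of transcript abundance that corrects for transcript length and library total, for 26830 gene symbols, as deposited by the authors in 1 table. STAR, RSEM and the GRCh38 build are named per the submitters' processing notes, while their versions and the gene annotation are not given in the sources used here. Every library sums to the same total, so TPM kept no sequencing depth, and the depth behind each value is unknown. A rise of a few abundant genes lowers the TPM of all others. An exact 0 can be a failed estimate, so such genes are described as listed at 0. RSEM divides reads among near-identical genes, and small RNAs, histone genes, readthrough transcripts and recent duplicates are therefore reported as uncertain. Of the symbols, 23842 were matched to GENCODE release 29 on GRCh38, which supplied coordinates, exon numbers, length and GC content. It may not be the annotation behind the table.

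Genes with at least 1 TPM in at least 2 libraries were tested, which left 11843 genes. Values were taken as log2(TPM + 1), and all fold changes are on that scale, which understates the change of low genes. The test was limma 3.58.1 in R 4.3.3, with 1 model over all 10 libraries, a variance trend and Benjamini-Hochberg (BH) adjustment within a comparison; a gene was called at an adjusted p below 0.05. The 8 comparisons were each dose against DMSO, each dose above 125 µM against the next lower dose, and a slope over dose levels from 0 to 4. Adjusted p-values in the text are from this fit unless another test is named. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

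The groups, tests, gene lists, rule for naming genes and most alternatives were set before the data were examined. The rule took the 12 largest rises and 12 largest falls at 1000 µM among called genes whose libraries did not overlap and whose higher group averaged at least 5 TPM. It took 4 per direction in the other comparisons, 6 per direction by smallest p for the slope, up to 4 members of each list by smallest p at 1000 µM, and 12 genes in every case. A few results, of this rule and of groups chosen later, are not reported here. There were 28 lists, of which 23 had the minimum of 5 tested genes. These were tested with camera at a correlation of 0.01, adjusted by BH over the lists, in all comparisons but 250 against 125 µM. Camera with an estimated correlation called no list in any of these 7 comparisons. In the fit of doses the estimates were 0.431 for the unfolded protein list, 0.479 for ATF4 genes and 0.546 for G2/M genes. Only the erythroid (0.0034) and interferon (−0.0829) lists lay below 0.01. Where the genes of a list move together more than the preset value allows, the camera p-value at 0.01 is too small. Alternatives were TMM scaling (factors computed on TPM, used for scaling only), quantile normalization, no filter, a mean of at least 5 TPM, a pseudocount of 0.1, a fit of the 2 compared groups alone, a fold threshold, the replicate number as a block and leaving out each library. Adjustment for GC content and length, the protein-coding subset and some genes marked in the text were chosen after the data were seen.

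The fit was tested on simulated values with 200 changed genes among 11843. For 1000 µM against DMSO it recovered 37.3% of changes of 0.5, 96.3% of changes of 1 and 100% of changes of 2 on the log2 scale, with 5.7% of calls false. For 125 µM the same shares were 39.4%, 95.7% and 99.7%, with 5.1% of calls false. The simulated noise was drawn independently for each gene from the fit's own spread, without shifts shared between genes or libraries. These shares therefore check the procedure and need not hold for the real libraries. Figures were drawn with Python 3 and matplotlib from the same tables.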

Results

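Expression was measured by RNA-seq in 10 libraries labelled MOLM-14, a myeloid leukaemia line that the series describes as carrying a FLT3 internal tandem duplication. They were 2 DMSO libraries and 2 at each of 125, 250, 500 and 1000 µM TFMB-2HG. The series asks whether a raised 2-HG level can by itself account for greater cell killing. Between 15395 and 15900 genes were listed above 0 in a library. Correlations across 11843 genes, which are not independent replicates, ranged from 0.9913 to 0.9962 within groups and from 0.9518 to 0.9609 between DMSO and 1000 µM libraries. The first principal component held 64.9% of the variance.

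All 10 libraries listed high levels of several globin and erythroid genes, but not of all. Adult HBB averaged 1.09 ± 0.566 TPM in DMSO (SD, n = 2). In DMSO, the fetal globin genes HBG2 and HBG1 averaged 30700 ± 962 and 16400 ± 934 TPM (SD, n = 2), embryonic HBE1 8250 ± 512 TPM, and the erythroid transcription factor genes GATA1 and KLF1 315 ± 8.14 and 196 ± 14.4 TPM. Genes of the labelled line were listed at or near 0: FLT3 did not exceed 0.02 TPM in any library, HOXA7, HOXA9, HOXA10 and S100A8 were listed at 0 in all 10, and S100A9 reached 0.23 TPM in 1. Of 22 fixed monocyte and macrophage genes, 19 stayed below 1 TPM in all libraries, as did 17 of 21 granule genes and 15 of 21 genes of the HOXA and MEIS1 programme. CD14 averaged 0.185 ± 0.0212 TPM and ITGAM 0.015 ± 0.00707 TPM in DMSO (SD, n = 2). The groups are therefore named by their labels throughout.

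**Figure D1:**
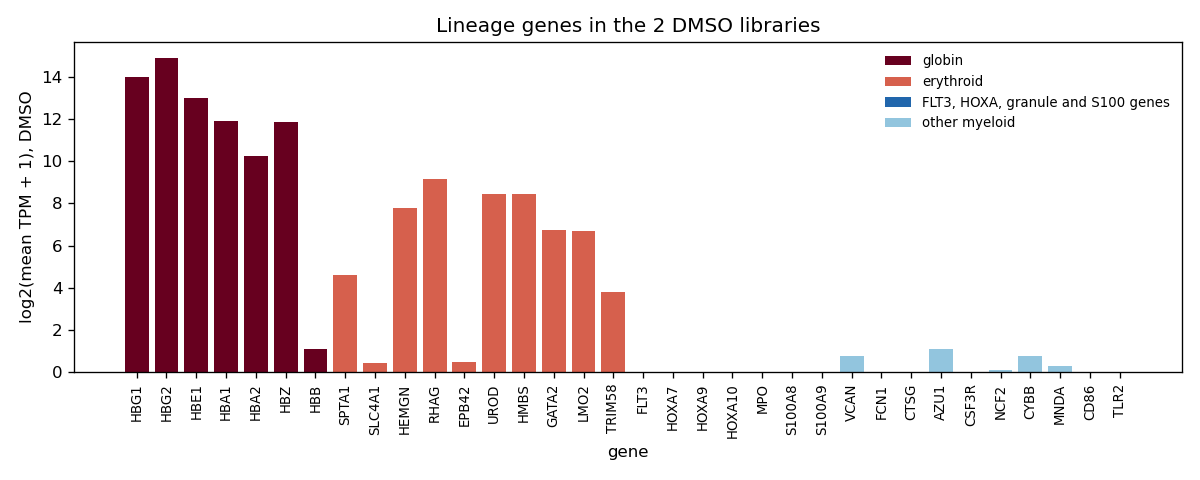
Mean of the 2 DMSO libraries for lineage genes (x axis), as log2(mean TPM + 1) on the y axis, coloured by gene set. HBG2 stands at 30700 TPM, while the bars of FLT3, the HOXA genes, MPO, S100A8 and S100A9 are at or near 0.

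At 1000 µM, genes of the endoplasmic reticulum (ER) stress response had several of the largest rises. HSPA5, the main ER chaperone (chromosome 9, 125234853 to 125241330, GRCh38), rose from 352 ± 7.64 to 2140 ± 17.3 TPM (SD, n = 2), a log2 fold change of 2.60 (SE 0.061, adjusted p = 5.3e-09). HERPUD1, which acts in ER-associated degradation (chromosome 16, 56932048 to 56944863), rose by 2.71 (SE 0.10, adjusted p = 9.5e-08), and DDIT3, the stress transcription factor CHOP (chromosome 12, 57516588 to 57521737), by 2.62 (SE 0.11), from 29.9 ± 4.04 to 188 ± 4.57 TPM. CHAC1, a glutathione-degrading enzyme, went from 1.08 ± 0.0495 to 9.99 ± 0.099 TPM. In all, limma with BH adjustment called 5928 of 11843 genes (50.1%), 2844 higher and 3084 lower, of which 435 and 595 changed at least 2-fold.

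The other large rises were VGF (2.16), the cornified-envelope gene SPRR2D (2.19) and the calpain gene CAPN5 (2.12). SNORA58, SCARNA13, SNORD3A, TMED7-TICAM2 and NME1-NME2 also met the rule, but they are small RNAs or readthrough transcripts whose reads are hard to assign. Among the falls, the thrombin receptor gene F2RL3 (chromosome 19, 16888860 to 16892606) went from 18.7 ± 1.58 to 0.745 ± 0.0778 TPM, a log2 change of −3.49 (SE 0.16, adjusted p = 2.8e-07). BGLT3, a non-coding gene of the beta-globin locus, fell by 3.43, TIGD5 by 2.74, OR51I1 by 2.69, the AP-1 gene FOSL1 by 2.67 and the formyl peptide receptor gene FPR3 by 2.65. LOC102724908 fell from 716 ± 54.3 to 62.3 ± 1.55 TPM. SMN2, nearly identical to SMN1, was listed at 11.04 and 10.96 TPM in the DMSO libraries and at 0 in both 1000 µM libraries. HIST1H4J (17.38 and 13.87 TPM in DMSO) and the duplicates MIR3648-1 and MIR3648-2 (90.04 and 19.02 TPM each) were also listed at 0 in both, and the readthrough IPO11-LRRC70 at 3.32 and 0 TPM; these 5 are uncertain. SNORA58 was listed at 0 in both DMSO libraries and at 4.24 and 15.74 TPM at 1000 µM. Without 1000 µM replicate 2, 3810 genes were called. The higher share, 48% in the fit of all libraries, was 37.9% and 56.3% without DMSO replicate 1 or 2.

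**Figure D2:**
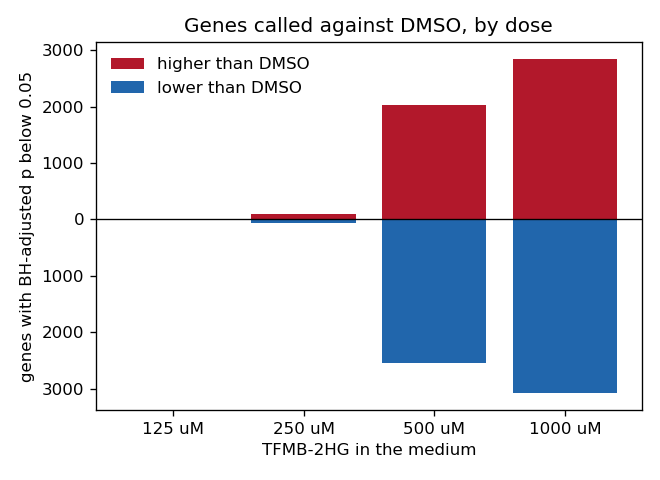
Genes called against DMSO (y axis, BH-adjusted p below 0.05) at each dose (x axis), with higher genes above 0 and lower genes below. Calls, from the fit without a replicate block, number 0 at 125 µM, 169 at 250 µM, 4568 at 500 µM and 5928 at 1000 µM.

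Of 19 genes of the ER unfolded protein response, 17 rose and 0 fell at 1000 µM, both over all genes and adjusted over the list alone. HSP90B1 rose by 1.63 (SE 0.061) and MANF by 1.92 (SE 0.088). Camera gave the list an adjusted p of 3.7e-09, against an adjusted p = 0.526 with an estimated correlation. Of 31 genes of the ATF4 and integrated stress list, 19 rose and 3 fell, the same counts as adjusted over the list alone. DDIT4 rose by 1.37 and the sestrin gene SESN2 by 1.99 (camera adjusted p = 0.000709; adjusted p = 0.819 with an estimated correlation). Of 20 p53 target genes 10 rose and 1 fell in both counts, among them GDF15 (1.64), the BH3-only gene BBC3 (1.09) and CDKN1A (0.78). The p53 list had a camera adjusted p of 0.0026, and an adjusted p = 0.819 with an estimated correlation. SESN2, BBC3 and GDF15 are also known targets of ATF4 or CHOP.

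Mitotic genes rose as well. Of 23 G2/M genes 14 rose and 0 fell, also when adjusted over the list alone, with KIF20A at 1.56 (SE 0.15), CDC20 at 0.97 and PLK1 at 0.92. Camera gave an adjusted p of 0.000518, and an adjusted p = 0.819 with an estimated correlation. Of 24 lysosome and autophagy genes 12 rose and 4 fell in both counts, with GABARAPL1 going from 20.8 ± 0.17 to 60.7 ± 5.73 TPM and the cathepsin gene CTSB at 0.79 (camera adjusted p = 0.021; adjusted p = 0.834 with an estimated correlation).

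Genes of ribosome production, glycolysis and the erythroid lineage fell. Of 22 MYC and ribosome biogenesis genes 19 fell and 0 rose, and 20 fell when adjusted over the list alone. NOP56, a nucleolar protein gene, went from 307 ± 13.8 to 97.6 ± 1.7 TPM (SD, n = 2), a change of −1.64 (SE 0.08), and PES1 fell by 0.96. MYC itself was at −0.02 (SE 0.14, adjusted p = 0.9). The list's camera adjusted p was 5.77e-07, with an adjusted p = 0.526 with an estimated correlation. Of 21 glycolysis genes 12 fell and 1 rose, or 13 and 2 adjusted over the list alone. The glucose transporter gene SLC2A1 fell by 1.46 and LDHA, encoding lactate dehydrogenase A, by 0.81 (camera adjusted p = 0.0026; adjusted p = 0.819 with an estimated correlation).

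Of 11 erythroid and megakaryocyte genes, listed as markers of another cell type, 8 fell and 1 rose, and 10 fell when adjusted over the list alone. KLF1 changed by −2.39 (SE 0.096, adjusted p = 1.2e-07), from 196 ± 14.4 to 36.6 ± 1.03 TPM. HBA2 fell by 1.04, HBA1 by 0.80 and HBG1 by 0.70, and these globin genes share sequence with close copies. Camera gave 0.000319 as adjusted p, and adjusted p = 0.19 with an estimated correlation. The globin share of TPM was 6.6% and 6.26% in the DMSO libraries and 3.64% and 3.69% at 1000 µM.

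**Figure D3:**
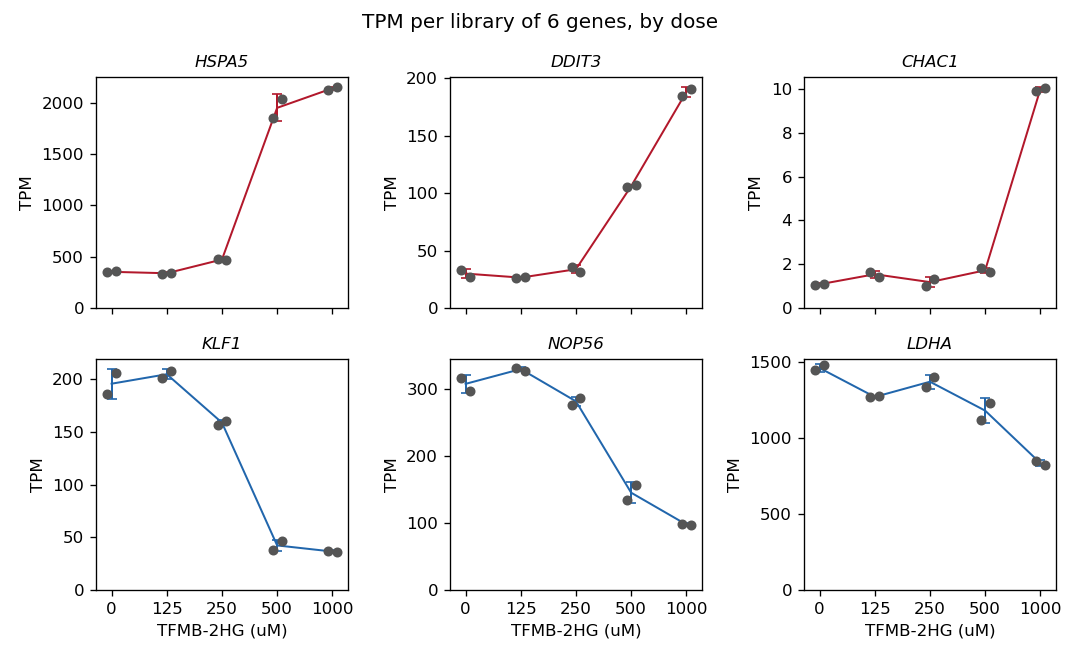
TPM (y axes, from 0) of 6 genes at each dose in µM (x axes, evenly spaced, 0 being DMSO); points are libraries, lines join group means and bars are SD of 2 libraries. HSPA5 is higher from 250 µM and DDIT3 from 500 µM, CHAC1 reaches 9.99 TPM at 1000 µM, and KLF1, NOP56 and LDHA are lower at 1000 µM than in DMSO.

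Genes of 2-HG metabolism moved in different directions at 1000 µM. IDH1 rose by 0.72 (SE 0.089, adjusted p = 0.00013), from 55.6 ± 2.74 to 92.1 ± 4.04 TPM (SD, n = 2), while IDH2 was at 0.19 (adjusted p = 0.058), after calls at 250 µM (0.38, adjusted p = 0.043) and 500 µM (0.36, adjusted p = 0.004). D2HGDH, which degrades D-2-HG, fell by 0.54 (adjusted p = 0.0045). Without 1000 µM replicate 1 the call of D2HGDH was lost (log2 fold change −0.40, adjusted p = 0.058). Of 35 tested genes of the tricarboxylic acid cycle and 2-HG metabolism 7 rose and 8 fell. Among 29 dioxygenase genes that use 2-oxoglutarate, 10 rose, with KDM6A at 0.87, and 3 fell, with the prolyl hydroxylase gene EGLN3 at −2.01. TET2 was at 0.23 (adjusted p = 0.19). Camera called neither list.

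The remaining tested lists were not called by camera at 1000 µM. Of 18 FLT3, STAT5 and MAPK feedback genes 8 rose and 2 fell, including rises of the kinase gene PIM1 (1.96, SE 0.095), CISH (1.71), FOS (1.58) and SOCS1 (1.21). FLT3 itself did not exceed 0.02 TPM in any library, so changes in this list cannot be read as FLT3 activity. Among 17 pro-apoptotic genes 6 rose and 4 fell, with APAF1 at 1.36 and PMAIP1 at 1.07, and among 7 anti-apoptotic genes 2 rose and 1 fell, with BIRC2 at 0.78 and MCL1 at −0.07 (adjusted p = 0.59). BCL2 stood at 0.46 ± 0.099 TPM in DMSO and was not tested. Of 22 hypoxia-inducible factor targets 5 rose and 7 fell, of 20 NRF2 targets 2 rose and 6 fell, with SRXN1 at −1.44 and SLC7A11 at 1.14, and of 24 replication genes 1 rose and 8 fell, with FEN1 at −0.60. Of 30 oxidative phosphorylation genes 10 fell and 0 rose. Cholesterol synthesis had 7 rises and 6 falls among 24 genes, fatty acid synthesis 3 and 3 among 13, inflammatory NF-κB genes 2 and 3 among 12, and interferon response genes 2 and 1 among 7. In the HOXA and MEIS1 list 1 of 6 tested genes rose, KIT (1.21), and in the epithelial and stromal list 3 of 5 fell and 1 rose, with EPCAM at −0.60. Lists with under 5 tested genes had 1 rise among 3 monocyte genes (KLF4, 1.12), 0 calls among 4 granule genes and 3 falls among 4 lymphoid genes, while no gene of MHC class II or of the mitochondrial genome was tested. Adjusted over the list alone, the counts in this and the preceding paragraph were the same except for 3 falls in oxidative phosphorylation, 5 among NRF2 targets and 3 among FLT3, STAT5 and MAPK feedback genes.

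At 500 µM the ER genes had already risen. HSPA5 reached 1950 ± 132 TPM (SD, n = 2), a log2 fold change of 2.46 (SE 0.061, adjusted p = 9.2e-09), HERPUD1 rose by 2.46 and DDIT3 by 1.80. The metallothionein gene MT1X rose by 2.21 (SE 0.085), from 325 ± 16.9 to 1510 ± 173 TPM, and the histone gene HIST1H2AH, one of a family of near-identical genes, by 2.29. F2RL3 fell by 3.57, LOC102724908 by 3.52 and TIGD5 by 2.92, and SMN2 was listed at 0. limma with BH adjustment called 4568 genes (38.6%), 2022 higher (44.3%) and 2546 lower. This balance was not stable: the higher share was 52.1% after quantile normalization and 53% with GC content and length adjusted, 55.3% and 31.6% without 500 µM replicate 1 or 2, and 32.8% and 55.2% without DMSO replicate 1 or 2.

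Camera called 5 lists at 500 µM. The ER unfolded protein list had 15 rises and 0 falls among 19 genes in both counts (adjusted p = 9.13e-11; adjusted p = 0.588 with an estimated correlation) and G2/M genes 12 rises among 23, or 13 adjusted over the list alone (adjusted p = 0.00107). Falls numbered 10 of 21 glycolysis genes, 13 of 22 ribosome biogenesis genes and 5 of 11 erythroid genes, or 11, 14 and 5 adjusted over the list alone. These 3 lists had camera adjusted p of 0.00462, 0.000818 and 0.00721. The erythroid list had an adjusted p = 0.515 with an estimated correlation, and the other 3 lists an adjusted p = 0.957 with an estimated correlation. Of the 31 ATF4 genes 8 rose and 9 fell, or 8 and 10 adjusted over the list alone (camera adjusted p = 0.917).

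Fold changes at 500 and 1000 µM against the shared DMSO libraries had a correlation of 0.82 across genes. In 100 simulations of unchanged groups and shared controls, with independent noise, it was 0.50, a value that sharing controls sets by itself. The covariance of the observed fold changes was 0.243 against a simulated 0.0129. The simulated controls held no shift of a whole DMSO library, so the simulation cannot show what such shifts add. Higher in both were 1564 genes, and lower in both 1992, where independent lists would share 486 and 663. Part of the excess may come from the shared controls.

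At 250 µM the metallothionein genes MT1X and MT2A rose. MT1X rose by 1.11 (SE 0.085, adjusted p = 0.00029) and MT2A, from 661 ± 25.7 to 1370 ± 83.9 TPM (SD, n = 2), by 1.05 (SE 0.08, adjusted p = 0.00029). C17orf49 rose by 1.15 and the adaptor gene GRB7 by 1.10, and HSPA5 by 0.42 (adjusted p = 0.017). The 4 largest falls were HIST1H4K (16.22 and 19.65 TPM in DMSO) and SMN2, both listed at 0 in the 2 libraries of this dose, and the signal recognition particle RNA genes RN7SL2 (−2.62) and RN7SL1 (−1.95), which have many close copies and spread widely in DMSO (4710 ± 2730 TPM for RN7SL2). The fit shared its spread over all groups, of which the 500 µM pair was the least alike (r = 0.9913) and the 1000 µM pair the most (r = 0.9962). In limma 169 genes were called, 102 higher (60.4%) and 67 lower. After TMM scaling 388 were called, with 70.9% higher, and with the replicate number as a block 929, with 54.5% higher. The count moved with every library left out: it was 11 and 35 without DMSO replicate 1 or 2, 54 without either 125 µM library, 5 and 8 without 250 µM replicate 1 or 2 (60% and 25% higher), 438 and 441 without 500 µM replicate 1 or 2, and 25 without either 1000 µM library. The calls of HSPA5, C17orf49, GRB7, RN7SL1 and RN7SL2 were each lost without 250 µM replicate 1, with an adjusted p of 0.13, 0.13, 0.072, 0.15 and 0.079.

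Camera called cholesterol synthesis (adjusted p = 0.000231) and fatty acid synthesis (adjusted p = 0.03) as lower at 250 µM. It called ER unfolded protein genes (adjusted p = 0.03), lysosome genes (adjusted p = 0.0423) and the epithelial and stromal list (adjusted p = 0.0423) as higher. Calls in these lists were few: 1 of 24 cholesterol genes fell, 0 of 13 fatty acid genes, 2 of 19 ER genes rose, 0 of 24 lysosome genes and 1 of 5 epithelial genes, and 5, 0, 4, 2 and 3 adjusted over the list alone. All 5 had an adjusted p = 0.942 with an estimated correlation.

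At 125 µM limma called 0 of 11843 genes. MT1X was at 0.61 (SE 0.085, adjusted p = 0.059), HSPA5 at −0.06 (adjusted p = 0.61) and KLF1 at 0.06 (adjusted p = 0.73). The smallest adjusted p was 0.0542, and 2553 genes (21.6%) had an unadjusted p below 0.05. After TMM scaling limma called 254 genes, 80.7% of them higher, and after quantile normalization 159, 69.8% higher. With the replicate number as a block, a pairing that the labels do not give but the libraries hint at, it called 2028 genes, 16.7% of them higher. With that block and GC content and length adjusted it called 446, 59.4% higher. The count and balance at this dose thus depended on the model. Leaving out a library gave 48 calls without 500 µM replicate 1 or 2, 8 and 9 without 250 µM replicate 1 or 2, 2 without DMSO replicate 2 and 1 without 125 µM replicate 2. The median of all genes lay at −0.103 at 125 µM. The fold changes given for this dose, and the calls of genes within lists, were not corrected for that shift. Camera called cholesterol synthesis and hypoxia-inducible factor targets as lower and the epithelial and stromal list as higher (adjusted p = 0.0102 for each; adjusted p = 0.983 with an estimated correlation), with 0 genes called and with 8, 3 and 3 adjusted over the list alone.

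**Figure D4:**
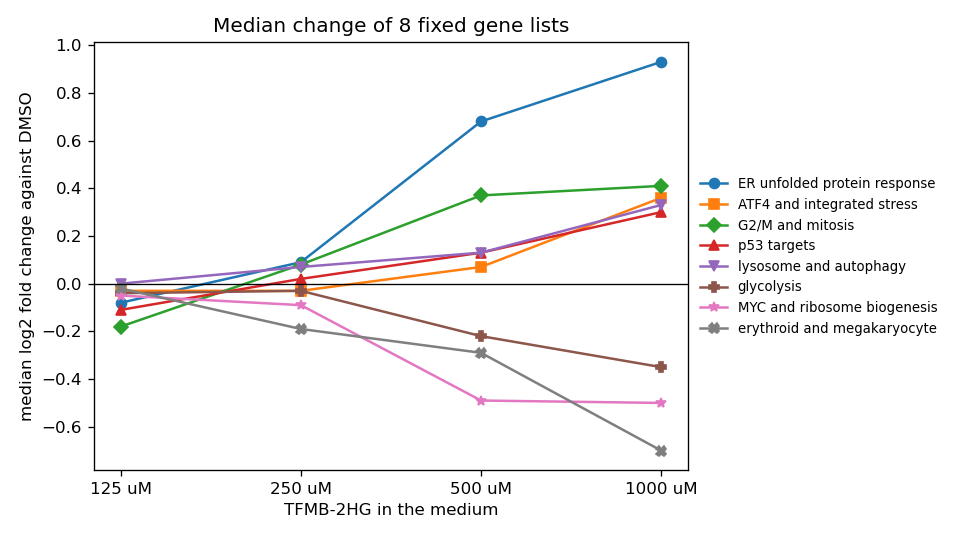
Median log2 fold change against DMSO (y axis) of the tested genes in the 8 lists that camera called at 1000 µM, at each dose (x axis, evenly spaced). The ER unfolded protein list reaches 0.68 at 500 µM and 0.93 at 1000 µM, and the erythroid list −0.70 at 1000 µM.

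Across dose levels, the egg-coat gene ZP3 had the smallest p among rising genes, from 3.29 ± 0.0283 TPM in DMSO to 13.4 ± 0.0495 TPM at 1000 µM (SD, n = 2; adjusted p = 3.3e-05). VGF, PSRC1, GRB7, UBALD2 and YPEL3 followed, with slopes of 0.52, 0.36, 0.54, 0.32 and 0.33 per dose level. FPR3 fell by 0.71 per level, RFESD by 0.43, the splicing factor gene SRSF7 by 0.42, TIMM8B by 0.40 and MAT2A, which makes S-adenosylmethionine, by 0.29. A called slope cannot tell a graded change from a step, and it counts DMSO to 125 µM as 1 level. HSPA5, at −0.06, 0.42, 2.46 and 2.60 over the 4 doses, had a called slope. So did MT1X, which was at 2.21 at 500 µM and 1.33 at 1000 µM. The slope was called in 5380 genes, 2713 rising and 2667 falling. Without the 1000 µM libraries it was called in 2210. Camera called ER genes (17 rising of 19, adjusted p = 3.88e-07), G2/M genes (14 of 23, adjusted p = 0.000817), p53 targets (9 rising and 1 falling of 20, adjusted p = 0.0113) and ATF4 genes (14 and 5 of 31, adjusted p = 0.0445), each with the same counts adjusted over the list alone. Falling were ribosome biogenesis (15 of 22, or 17 adjusted over the list alone; adjusted p = 8.77e-06), erythroid (8 of 11 in both counts; adjusted p = 0.0022) and glycolysis genes (13 of 21, or 14; adjusted p = 0.00352). In the order given, these 7 lists had an adjusted p = 0.696, 0.696, 0.715, 0.789, 0.629, 0.629 and 0.696 with an estimated correlation.

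Between neighbouring doses, most calls lay between 250 and 500 µM. There 3504 genes were called, 1458 higher (41.6%) and 2046 lower; HERPUD1 rose by 2.40 and HSPA5 by 2.04, F2RL3 and LOC102724908 each fell by 2.97 and TIGD5 fell by 2.54. The small RNA gene SNORD3A (3.04), HIST1H4K, listed at 0 at 250 µM, and LOC105372493, listed at 40.57 and 33.57 TPM at 250 µM and at 0 in both 500 µM libraries, also met the rule and are uncertain. Of the 19 ER genes 15 rose, or 16 adjusted over the list alone (camera adjusted p = 6.15e-12; adjusted p = 0.499 with an estimated correlation), and of 24 cholesterol genes 10 rose and 1 fell, or 10 and 2 (camera adjusted p = 0.00997; adjusted p = 0.91 with an estimated correlation). Camera also called ribosome biogenesis (11 of 22 fell), glycolysis (8 of 21 fell), erythroid (6 of 11 fell), G2/M (5 of 23 rose) and FLT3, STAT5 and MAPK feedback genes (6 of 18 rose). The erythroid list had an adjusted p = 0.499 with an estimated correlation, and the other 4 an adjusted p = 0.91 with an estimated correlation. Without 250 µM replicate 1 or 2 the count of genes was 1903 and 1690, and with GC content and length adjusted 51.7% of calls were higher. The higher share was 53.5% and 27.1% without 500 µM replicate 1 or 2. Between 125 and 250 µM 5 genes were called: AMN1 (0.92), HSPA5 (0.48) and HSP90B1 (0.44) rose, while SMN2 and HIST1H4K fell to a listing at 0. The higher share of 60% became 34.2% of 38 calls after TMM scaling and 42.6% of 47 after quantile normalization. The calls of AMN1, HSPA5 and HSP90B1 were lost without either DMSO, either 125 µM, either 250 µM or either 1000 µM library. The count was then 1 without either DMSO library, 1 and 3 without 125 µM replicate 1 or 2, 3 and 2 without 250 µM replicate 1 or 2, and 1 without either 1000 µM library, against 22 and 27 without 500 µM replicate 1 or 2.

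From 500 to 1000 µM the ATF4 and integrated stress list rose. Of its 31 genes 14 rose and 0 fell, and 19 rose adjusted over the list alone (camera adjusted p = 2.02e-10; adjusted p = 0.894 with an estimated correlation). CHAC1 rose by 2.01 (adjusted p = 0.0001), and of the 19 ER genes 2 rose and 1 fell (camera adjusted p = 0.333). RN7SL2 rose by 3.68 and RN7SL1 by 2.58, against their falls at 250 µM. HIST1H4J, MIR3648-1, MIR3648-2, IPO11-LRRC70 and SNORA58 met the rule and are uncertain as above. Camera further called p53 targets (4 of 20 rose), 2-oxoglutarate dioxygenases (1 rose and 1 fell of 29) and lysosome genes (1 and 1 of 24) as higher. It called ribosome biogenesis (1 rose and 7 fell of 22), erythroid (2 of 11 fell) and epithelial and stromal genes (2 of 5 fell) as lower. Of these the erythroid list had an adjusted p = 0.615 with an estimated correlation, and the others an adjusted p = 0.894 with an estimated correlation. In all 1629 genes were called, 704 higher (43.2%) and 925 lower. Without 1000 µM replicate 1 or 2 the count was 380 and 285, with 31.8% and 25.3% higher. Without 500 µM replicate 2 it was 2655, with 70.1% higher, and without 500 µM replicate 1 the higher share was 26.5%, so the balance depended on single libraries.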

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

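The adjustments for GC content and length and the protein-coding subset were chosen after the data were seen; the other settings were set beforehand. In the order 125, 250, 500 and 1000 µM against DMSO, then 250 against 125, 500 against 250 and 1000 against 500 µM, limma called 0, 169, 4568, 5928, 5, 3504 and 1629 genes. No called named gene or list changed direction, but the balance of higher and lower calls did turn in some settings. The main fit did not scale libraries, whose TMM factors ran from 0.9215 (125 µM replicate 1) to 1.081 (DMSO replicate 2). At 500 µM against DMSO the median log2 change of all genes was −0.0217 in that fit and 0.0128 after TMM scaling. It was 0.0644 and −0.102 without 500 µM replicate 1 or 2. The higher share at that dose, given above, rose and fell with this median. Below are the counts that moved by over 1.5 times; the cause was not tested unless fewer libraries or a stricter threshold explains them. TMM scaling gave 254, 388, 38 and 2858 for 125, 250, 250 against 125 and 1000 against 500 µM, and quantile normalization 159, 659, 47 and 3166. Without a filter, counts were 2, 14 and 2 for 125, 250 and 250 against 125 µM. A pseudocount of 0.1 gave 1 at 125 µM. Fitting the compared groups alone gave 30, 2961, 137, 1541 and 358 for 125, 500, 250 against 125, 500 against 250 and 1000 against 500 µM. A log2 change of at least 1 left 10, 586, 1030, 2, 310 and 103 for all but 125 µM. Adjusting GC content and length gave 21, 1321, 274 and 3584 for 125, 250, 250 against 125 and 1000 against 500 µM, and the protein-coding subset 6 at 125 µM. The slope was called in 2210 genes without the 1000 µM libraries, against 5380.

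The labels do not say that replicate numbers pair the libraries, and they were not treated as pairs: correlations of same-numbered libraries' deviations from their group means ran from −0.003 to 0.407 over 10 pairs of groups, 4 of them at or under 0.1. The data nevertheless point to a part shared by number. In all 5 groups replicate 2 lay above replicate 1 on the first and the second principal component. It also had the larger TMM factor and the lower ribosomal protein share of TPM in each group. That share was 33.7% against 36.6% at 500 µM and 34.8% against 35.5% at 1000 µM. The counts from the fit without a block take no account of this. By the deviations from group means, which mirror each other within a group of 2, 10 of 10 libraries were closest to their own number in another group. By the correlation of whole values this was not so for every library: DMSO replicate 1 had 0.9937 with 125 µM replicate 2 and 0.9918 with 125 µM replicate 1. With the replicate block, 2028, 929, 855, 5340 and 3549 genes were called for 125, 250, 250 against 125, 500 against 250 and 1000 against 500 µM, of which 16.7%, 54.5%, 80.7%, 45.6% and 54.3% were higher. With the block and GC content and length adjusted, these were 446, 2001, 764, 5350 and 4255, with 59.4%, 54.5%, 44.8%, 52.5% and 49.5% higher, so the balance under the block turned in all of these but 250 µM.

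Leaving out 1 library, which assumes that the lone sample varies like the other groups, gave 0 to 48 calls at 125 µM, 5 to 441 at 250 µM, 3333 to 4558 at 500 µM and 3810 to 6647 at 1000 µM. The ranges were 3815 to 5933 for the slope, 1 to 27 for 250 against 125 µM, 1690 to 3803 for 500 against 250 µM and 285 to 2655 for 1000 against 500 µM. Camera called 8 lists at 1000 µM and 8 to 10 without 1 library. It called 0 with an estimated correlation, and fry, which asks only whether the genes of a list move one way, called 13. Depth is unknown, so counting error cannot be given for any gene.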

Other observations

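The gene groups in the first 2 paragraphs, and the tests of mixed cells, of a mislabelled sample and of GC content and length at 125 µM, were chosen after the values were seen. Camera p-values of these groups are therefore descriptive. The metallothionein genes MT1X, MT2A, MT1G and MT1E, whose products bind zinc and copper, rose at 500 µM, and from 500 to 1000 µM MT1X fell by 0.88 (adjusted p = 0.000494) and MT2A by 0.37 (adjusted p = 0.0158). MT2A averaged 661 ± 25.7 TPM in DMSO, 2410 ± 175 TPM at 500 µM and 1870 ± 128 TPM at 1000 µM (SD, n = 2), and MT1G 21.7 ± 0.24, 86 ± 7.87 and 68.4 ± 6.06 TPM. MT1F averaged 0.46 ± 0.127 TPM in DMSO and 0.325 ± 0.46 TPM at 500 µM, and MT1H 3.55 ± 2.22 and 4.46 ± 2.96 TPM. At 1000 µM 5 of 6 tested members were called higher in limma and 0 lower (camera adjusted p = 0.000344; adjusted p = 0.476 with an estimated correlation). Of 25 genes of ER to Golgi transport 16 rose and 0 fell, with the coat genes SEC24D at 2.02 (SE 0.20) and COPB1 at 0.97 (SE 0.10). Camera gave an adjusted p of 8.16e-05, and an adjusted p = 0.476 with an estimated correlation.

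Erythroid regulators fell at 1000 µM in 7 of 11 tested genes and rose in 0 (camera adjusted p = 0.000344; adjusted p = 0.476 with an estimated correlation). GFI1B went from 65.2 ± 5.08 to 13.8 ± 0.191 TPM (SD, n = 2), NFE2 from 289 ± 8.61 to 93.3 ± 1.58 TPM and LMO2 from 103 ± 7.32 to 27.5 ± 3.14 TPM, while GATA1 fell by 0.58 on the log2 scale. TAL1 and MYB were at 0.11 and 0.17 and were not called. Camera did not call cytosolic chaperones (1 rise and 6 falls of 15) or tubulins (3 rises and 5 falls of 8).

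All 10 libraries listed several globin and erythroid genes high and the labelled line's genes near 0. Erythroid cells mixed into that line would bring its FLT3, HOXA7, HOXA9, HOXA10, MPO, S100A8 and S100A9 transcripts, whose highest value in any library was 0.23 TPM. A single mislabelled sample would leave other libraries without globin, yet 10 of 10 exceeded 1000 TPM for HBG1, HBG2 and HBE1. A candidate explanation, formed after the globin genes were seen, is that all libraries come from an erythroid line. Of 10 further erythroid genes chosen before their own values were seen, 8 exceeded 5 TPM in DMSO. SLC4A1 and EPB42 did not, at 0.32 and 0.395 TPM. Of 10 myeloid genes 9 lay below 1 TPM, the other being AZU1 at 1.1 TPM. Leukocyte or myeloid genes noticed after their values were seen were nevertheless present in DMSO: CD68 at 81, PTPRC at 50.3, CD33 at 35.1, SPI1 at 27.1 and LYZ at 20.9 TPM. No reference profile of any line was compared, so which line it may be stays open, and no biological explanation within the design was tested.

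Single-exon protein-coding genes lay lower at 1000 µM than multi-exon genes, by −0.34 on the log2 scale (95% bootstrap interval −0.44 to −0.24, 253 of 10502 genes, which are not independent). They were the end of a gradient at that dose. Median log2 changes were −0.27 for 1 exon, −0.19 for 2, −0.12 for 3 and −0.04 for 4 to 5. For 13 to 20 exons the median was 0.07 and for over 20 it was 0.23. At 125 µM the order of these ends was reversed, with −0.1 for 1 exon and −0.21 for over 20. At 250 µM they were −0.04 and −0.03, and at 500 µM −0.24 and 0.03. With GC content in the model the single-exon difference at 1000 µM was −0.31 and with transcript length −0.27, which argues against either as the whole cause. With GC content, length and mean level together it was −0.25. Genomic DNA reads, more of them in DMSO libraries, could add to single-exon genes: summed TPM of 330 olfactory receptor genes, without the OR51 and OR52 families of the globin locus, was 25.1 in DMSO and 14.4 at 1000 µM, and the lowest DMSO sum exceeded the highest 1000 µM sum by 10 TPM, as that explanation needs. Among genes with a mean of at least 10 TPM, where such reads would weigh less, the difference was −0.38 (−0.51 to −0.25), which argues against DNA as the source at those genes. The 95th percentile of these receptor genes was 0.193 TPM in DMSO against a median fall of 7.89 TPM in the 113 single-exon genes called lower, but genes so near 0 exclude nothing, so DNA reads stay open for low genes; the cause of the gradient among genes with several exons was not tested, and an effect of the treatment tied to exon number stays open.

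At 125 µM 21.6% of genes had an unadjusted p below 0.05 with 0 calls after adjustment, in the fit without a replicate block. Fold changes at this dose had a correlation across 10502 protein-coding genes of 0.63 with GC content and −0.38 with log2 length. With GC content the correlation was 0.23 at 250 µM, −0.3 at 500 µM and −0.15 at 1000 µM, so its sign changed between 250 and 500 µM. After each library's trend with GC content and length was removed, 18.6% of the genes with known GC content and length still had an unadjusted p below 0.05, which argues against these trends as the whole cause. The test is a weak one, since at 250 µM the same removal raised this share from 15.8% to 28.7%. A small response at 125 µM may remain, and with 2 libraries per group it was not separated from other differences between libraries.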
